A study of Mus musculus with 4 samples.

How the data were processed

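Strand-specific RNA sequencing of fetal mouse gonads at 15.5 days post coitum (dpc) was analysed from 4 libraries, 1 for each combination of sex and sorted fraction. CF1 mothers had been mated with TgOG2 fathers, whose transgene drives green fluorescent protein (GFP) from the Oct4 (Pou5f1) promoter in germ cells. Per the labels' protocols, GFP-positive germ cells and GFP-negative gonadal somatic cells were separated by flow cytometry, RNA was extracted with a phenol-based reagent and treated with DNase, ribosomal RNA was depleted, and paired-end libraries were sequenced. With ribosomal depletion, transcripts without a poly(A) tail, such as replication-dependent histone mRNAs, stay in the library.

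The submitters' processing notes name CASAVA 1.9, TopHat 1.2.0, edgeR without a version, and the mm9 build, with no role or order. The program that assigned reads to genes, the gene annotation and the use of strand in counting are not given in the sources used here. Each file listed chromosome, start, end, strand, symbol, length and a value for the same 20373 gene rows. The deposited values are a gene-level read signal, although the file headers name the column counts. They are whole numbers, but low values cluster at a fixed spacing of 4.105 in the male germ and female somatic libraries, 6.07 in the female germ library and 6.11 in the male somatic library. In the female germ and male somatic libraries 11 of the values from 1 to 60 never occur. The library totals lie close together, from 99.4 to 107.6 M, where M stands for 1000000. The deposited signal was therefore treated as scaled by 1 factor per library and rounded, a step whose reason is not given in the sources used here.

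The spacing was taken as the worth of 1 sequenced fragment. By this measure the depth was 24.9 M fragments in the male germ library, 17.5 M in the female germ library, 17.6 M in the male somatic library and 24.2 M in the female somatic library. Between 43.2% and 54.2% of the nonzero values up to 60 lay within rounding of a multiple of the spacing, against 16.4% to 24.4% by chance. Why the other values lay off the spacing was not tested. Fragment numbers are rounded estimates for that reason, and intervals and floors built on them cover counting error only. PCR copies could not be told from separate molecules. A gene listed at 0 was set against a floor of 3 fragments per library, worth 0.113, 0.179, 0.180 and 0.120 SPM (scaled signal per 1000000) in the order above.

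Rows that repeated a position and all 4 values were kept once, which removed 74 rows and left 20299 genes. Of these, 1596 were listed at 0 in every library and 15581 reached 1 SPM in at least 1 library. Signals were divided by library totals adjusted with trimmed-mean-of-M (TMM) factors of 1.07, 0.956, 0.945 and 1.03 for male germ, female germ, male somatic and female somatic, and are given in SPM. They were not divided by gene length, so levels compare libraries and not genes. Reads of near-identical copies cannot be assigned to a single copy. The listed values of Hba-a1 and Hba-a2 were identical in both germ libraries and nearly so in the somatic libraries, and members of multigene families are uncertain in the same way.

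The comparisons, gene lists, size rules and most alternatives were fixed before the data were examined. That plan assumed raw counts and a count-based quasi-likelihood test. Because the values are not counts, limma 3.58.1 in R 4.3.3 with a mean-variance trend and Benjamini-Hochberg adjustment was used on log2(SPM + 0.5) instead, with a threshold of 0.05, over genes at 1 SPM or more in at least 2 libraries. Fold changes on this scale understate differences of low genes. Germ against somatic was fitted with the 2 sexes as the samples of each cell type, which leaves 2 residual degrees of freedom. The sex difference shared by both cell types was fitted with cell type as a term, which leaves 1. Nothing in the labels says that the libraries came from separate animals, so p-values measure only the spread between these libraries.

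Male against female germ cells, and male against female somatic cells, set 1 library against 1, so these ratios have no replicate check and no p-value is given. Genes were counted by a fixed rule of at least 4-fold and at least 5 SPM in the higher library. Ratios carry an exact conditional binomial 95% interval. Where a library was listed at 0 the fold was taken against its floor and written as at least N-fold. For gene lists the median log2 ratio of the members at 1 SPM or more is given, with its percentile among 10000 random lists of the same size matched on mean level, which describes these libraries alone. Genes detected per library were counted after drawing every library down to the smallest depth, as the mean of 100 draws. Biotypes came from symbols and synonyms in a GRCm38.p6 gene table, which matched 20147 of the 20299 genes. All coordinates are mm9 as the files list them.

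Named genes followed a fixed rule. In each comparison they were the 5 genes with the largest ratio of SPM + 0.5 in each direction among those with at least 20 SPM in the higher library (for germ against somatic in both libraries of the higher type, and past the test), leaving out gene-model symbols. To these were added the first 3 measured members of the lists tied to the comparison, and any list member that went 4-fold or more against its list. For the shared sex difference, the passing genes with the 10 smallest p-values were named. A gene named outside this rule is marked where it first appears, except as a list example.

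Alternatives replaced the TMM factors by median-of-ratios factors, library totals or the upper quartile, removed the filter, changed the terms of the model, left out each library in turn, changed the size and level limits, changed the pseudocount for list medians, and changed how detection was counted. Pseudocounts of 0.1 and 2 in the limma fits, the values as deposited without further scaling, and male against female somatic cells without genes of the germ, blood and endothelial lists were chosen after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

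The procedures were tested on simulated data. In the germ against somatic fit, with 200 changed genes among 13952 to 13996 tested and a coefficient of variation of 0.1, 93.5% of 2-fold and 100% of 4-fold and 8-fold changes were recovered. At a coefficient of 0.4 the share was 0% of 2-fold, 27% of 4-fold and 88.5% of 8-fold changes, and between 0 and 19 unchanged genes passed over the 6 runs. The run with 19 recovered all 200 changed genes. These simulations held no sex difference, whereas in the data the sexes are the samples of each cell type. They therefore do not give the recovery for genes that differ between the sexes. For male against female germ cells, the size rule made 0 calls among 20299 genes under counting error alone and recovered 200 of 200 genes set 8-fold higher. For genes detected per library, a single profile simulated at 2 depths gave detection counts within 0.266% of each other after thinning.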

Results

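Gene-level RNA signal was measured in flow-sorted germ cells and gonadal somatic cells of male and female mouse fetuses at 15.5 dpc, with 1 library in each of the 4 groups. At this age male germ cells have entered mitotic arrest and female germ cells are in meiotic prophase. The study's title is about transcription in male germ cells, wide in reach and low in level, before their DNA is methylated, and the design text states that transcription was mapped in all 4 fractions. As a check on the sort, Pou5f1, whose promoter drives the GFP reporter, stood at 497 SPM in male germ cells, 34.5 in female germ cells, 4.75 in male somatic cells and 0.0195 in female somatic cells, the last below the floor of 3 fragments. Levels are scaled signal per 1000000 (SPM), and M stands for 1000000. Depth ranged from 17.5 to 24.9 M fragments.

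Germ cells were compared with somatic cells to describe what sets the sorted fractions apart. Most genes of germ cell identity and of the piRNA pathway were far higher in both germ libraries, and most genes of the gonadal stroma and of red blood cells were far higher in both somatic libraries. Exceptions included Nanos3, a germ cell survival gene, at 22.3 SPM in male germ cells but 1.005 in female germ cells against 1.06 and 2.07 in male and female somatic cells. Stk31, a germ cell tudor-domain kinase gene (chromosome 6, 49345602 to 49419501), stood at 1691 and 1508 SPM in male and female germ cells against 7.44 and 2.77 in male and female somatic cells, a log2 ratio of 8.29 ± 0.55 (SE; n = 2 libraries per cell type, limma adjusted p = 0.0328). Dazl, a germ cell RNA-binding protein gene (chromosome 17, 50418718 to 50432924), rose by 8.25 ± 0.50, Asz1, a germ granule protein gene, by 7.93 ± 0.85, Mov10l1, the piRNA helicase gene, by 7.82 ± 0.70 and Slc25a31, a mitochondrial ADP/ATP carrier gene, by 7.81 ± 0.51, each with a limma adjusted p of 0.0328.

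In the other direction, Col1a2, which encodes a type I collagen chain (chromosome 6, 4455696 to 4491543), reached 5583 and 1570 SPM in male and female somatic cells against 43.7 and 8.79 in germ cells, a log2 ratio of -7.19 ± 0.97 (limma adjusted p = 0.0352). Islr, which encodes a secreted leucine-rich repeat protein, gave -7.45, the membrane protein gene Emp1 -6.95, the embryonic globin gene Hbb-y -7.15 and the adult globin gene Hbb-b1 -6.94. All 4 passed, with limma adjusted p between 0.0328 and 0.0341. The globins show that red blood cells were part of the GFP-negative fraction: Hbb-b1 took 1.49% of the whole male somatic signal and was its highest gene.

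Of the 9 measured genes of the germ cell core list, 6 passed as higher in germ cells and none as lower, or 7 when adjusted over the list alone. Ddx4, the germ cell RNA helicase gene, rose by 7.78 ± 0.84 (limma adjusted p = 0.0328), whereas Dnd1, at 236 SPM in male and 6.65 in female germ cells, did not pass (adjusted p = 0.240). Of 17 piRNA pathway genes, 12 rose, or 15 adjusted over the list alone. Of 14 measured pluripotency genes, 13 could be tested and 5 rose, or 12 adjusted over the list alone, with Sox2 at 4.53 ± 0.86 (limma adjusted p = 0.0447). Dppa3 had a ratio of 6.51 and did not pass (adjusted p = 0.0621), with 599 SPM in male and 36.2 in female germ cells. Nanog, with a ratio of 2.03, was the gene not tested. Of 19 meiosis genes 7 rose, or 15 adjusted over the list alone. The oocyte list had 1 passing member among 11 tested, Taf4b (adjusted p = 0.0347), or 5 adjusted over the list alone.

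Of 11 stroma genes, 9 were lower in germ cells, or 11 adjusted over the list alone, with a median log2 ratio of -6.33. Collagen I gene Col1a1 had -6.48 ± 0.81 (limma adjusted p = 0.0336) and Nr2f2, a transcription factor gene of steroidogenic stroma, -4.93 ± 0.84 (adjusted p = 0.0386). Pdgfra, at -6.05, did not pass (adjusted p = 0.0524). Of 9 tested erythroid genes 7 fell, or 8 adjusted over the list alone. Early response genes such as Fos, at 298 and 701 SPM in male and female somatic cells against 6.51 and 14.3 in germ cells, fell in 7 of 12 cases, or 10 adjusted over the list alone. None of 15 Sertoli, 7 tested fetal Leydig or 4 tested escape genes passed over all genes, while 3 Sertoli, 3 Leydig and 1 escape gene passed as lower adjusted over the list alone. Of the Sertoli genes, Amh, Sox9 and Dhh gave log2 ratios of -1.97, -2.80 and -2.48, and Dmrt1 went against its list at 2.33. Among 9 tested pregranulosa genes Wnt4 fell by 5.30 on the log2 scale (adjusted p = 0.0336), and 3 fell adjusted over the list alone. Fst, at -2.17, did not pass over all genes, and Foxl2, at -1.84, was not tested. Endothelial genes fell in 1 of 12 cases and leukocyte genes in 1 of 8, or in 5 and 6 adjusted over each list alone.

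Paternally expressed imprinted genes fell in 7 of 22 cases, or 12 adjusted over the list alone, with a list median of -2.26, or -2.66 with the member listed at 0 set at its bound. Igf2, the growth factor gene (chromosome 7, 149836672 to 149846940), stood at 14.6 and 27.5 SPM in male and female germ cells against 319 and 581 in somatic cells, a log2 ratio of -4.39 ± 0.54 (limma adjusted p = 0.0336). Peg3 gave -3.50 ± 0.54 (adjusted p = 0.0358). Snrpn, at 0.72, and Rasgrf1, at 3.10, did not pass (adjusted p = 0.473 and 0.132). Of 10 maternally expressed genes 2 fell and 2 rose, or 3 and 3 adjusted over the list alone. The genes that rose were Phlda2 (3.59 ± 0.61, limma adjusted p = 0.0386) and Slc22a18 (3.31 ± 0.63, adjusted p = 0.0452), neighbours on chromosome 7. Grb10 had -2.88, Cdkn1c -2.21 and Igf2r -0.77, none passing (limma adjusted p = 0.0572, 0.296 and 0.448). Ascl2 went against this list at 2.08 without passing. Of 16 proliferation genes Bub1, a mitotic checkpoint kinase gene, rose (3.76 ± 0.75, adjusted p = 0.0484), and none did adjusted over the list alone. None of the genes for DNA methylation (16), H3K4 methyltransferase complexes (11) or H3K4 demethylases (7) passed, over all genes or adjusted over each list alone. Dnmt3l (3.49) and Ctcfl (2.74) went against the DNA methylation list, and Lhx1 (2.43) against the mesonephric duct list. Of 66 histone genes 46 were at least 2-fold lower in germ cells (median -1.20) and 2 passed as lower. Hist1h1t (3.08), Hist1h2ba (5.36) and Hist1h2aa (4.84) were higher in germ cells without passing.

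Over all 14148 genes tested with limma, 1140 passed at an adjusted p under 0.05, 354 higher and 786 lower in germ cells. With sex as a term, 3049 passed, 1094 higher and 1955 lower, among them Dnd1, Dppa3, Pdgfra, Rasgrf1, Grb10 and Cdkn1c. That fit removes the shared sex difference from the spread and leaves 1 residual degree of freedom. The degrees of freedom borrowed from other genes rose from 3.15 to 25.7, so it took most of its spread from other genes. Dnd1 passed although its log2 sex difference was 5.04 in germ and 0.09 in somatic cells, and so hardly shared. In the fit without sex as a term the spread was taken between the sexes, so genes that differ strongly between male and female germ cells had large errors. The list counts above come from this fit alone and were not made with sex as a term. Without the male somatic library 349 genes passed, without the female somatic library 399, without the female germ library 2369 and without the male germ library 4262. With no filter on low values, 0 of 18703 genes passed limma, with 4625 at an unadjusted p under 0.05.

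Male and female germ cells were compared because their programs part at this age. Male germ cells held the genes of the male pathway and of pluripotency, and 14 of 17 of piRNA production, at higher levels, and female germ cells held the genes of meiosis and the histones. Dnmt3l, the cofactor of de novo DNA methyltransferases (chromosome 10, 77505031 to 77526360), stood at 425 SPM in male and 0.187 in female germ cells, a ratio of 2270 with a counting interval of 811 to 11492 on 3 fragments in the female library. Nanos2, a repressor of meiosis in male germ cells (chromosome 7, 19572872 to 19574311), stood at 60.6 SPM in male germ cells and was listed at 0 in female germ cells, at least 338-fold higher. Stra8, which is induced at meiotic entry (chromosome 6, 34870959 to 34889342), was 53.5-fold higher in female germ cells (43.1 to 67.2), at 171 against 3.19 SPM.

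All 7 measured genes of the male germ program were at least 2-fold higher in the male library, with a median log2 ratio of 3.90 at percentile 99.99 of matched random lists, or 5.27 with the 3 members listed at 0 set at their bound. Lefty1, a Nodal pathway inhibitor gene, stood 29.99-fold higher (14.6 to 67.7) and Piwil4, the nuclear piRNA-binding protein gene, 191-fold higher (144 to 256.0). Of 14 pluripotency genes, 12 were at least 2-fold higher in the male library and none in the female (median 2.60, percentile 100), among them Nanog at 14.7-fold (8.43 to 29.3), Sox2 at 4.06-fold (3.28 to 5.10) and Dppa3 at 16.6-fold (15.3 to 17.98). In the piRNA pathway 10 of 17 genes were at least 2-fold higher in the male library and none in the female (median 1.41, percentile 99.87). Piwil2 stood 4.81-fold higher (4.67 to 4.95), while Mov10l1 differed by 1.25-fold (1.23 to 1.28). Among germ cell core genes the X-linked Taf7l went against its list, 12.03-fold higher in the female library (11.5 to 12.6).

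All 19 measured meiosis genes were at least 2-fold higher in the female library (median -3.38, percentile 0). The synaptonemal complex genes Sycp3 and Sycp1 were 9.34-fold (8.84 to 9.88) and 10.9-fold (10.5 to 11.5) higher. The oocyte list split, with 7 of 14 genes at least 2-fold higher in the male library and 4 in the female (median 0.63, percentile 42.1). Figla, Sohlh2 and Lhx8, transcription factor genes of early oocytes, were 18.3-fold (14.7 to 23.1), 15.1-fold (13.4 to 17.03) and 5.35-fold (3.79 to 7.80) higher in the female library, and Nobox 2.47-fold (1.70 to 3.62). The oocyte genes higher in the male library included Sohlh1, at 69.0 against 4.15 SPM, and Ooep, at 16.8 against 2.37.

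Of 66 replication-dependent histone genes, 60 were at least 2-fold higher in the female germ library and none in the male (median -2.74, percentile 0). The testis-type histone gene Hist1h2ba (chromosome 13, 24025641 to 24026025), which was also among the largest differences of all, was 185-fold higher (150 to 231). Proliferation genes were mixed, with 7 of 16 at least 2-fold higher in the female library and 3 in the male (median -0.58, percentile 14.3). Mki67 and Top2a stood 16.1-fold (15.2 to 17.1) and 3.42-fold (3.35 to 3.48) higher in the female library, while the mitotic cyclin gene Ccnb1 and Aurkb were 6.22-fold (5.54 to 6.99) and 5.16-fold (3.72 to 7.51) higher in the male library.

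For the enzymes that write and erase DNA and H3K4 methylation, single genes differed between germ cells of the sexes, in both directions within each list. Among DNA methylation genes 5 of 16 were at least 2-fold higher in the male library and 1 in the female (median 0.08, percentile 70.4). Dnmt3a, a de novo methyltransferase gene, was 9.89-fold higher in the male library (9.23 to 10.6), at 516 against 52.2 SPM, with 494 and 538 in male and female somatic cells. Dnmt3b was 3.04-fold higher in the male library (2.60 to 3.55), and Dnmt1, the maintenance enzyme, 1.67-fold higher in the female (1.62 to 1.72). The H3K4 methyltransferase genes, with 2 of 11 members at least 2-fold higher in each sex (median 0.14, mean -0.12, percentile 81.0), included Mll1 at 1.94-fold (1.85 to 2.04), Wbp7 at 1.70-fold (1.61 to 1.79) and Setd1a at 1.80-fold (1.72 to 1.89), all higher in the female library. Among H3K4 demethylase genes 2 of 7 were at least 2-fold higher in each sex (median -0.43, mean 0.05, percentile 30.5). Kdm1b, which acts in oocyte imprinting, was 6.63-fold (6.29 to 6.99) and Kdm1a 3.14-fold (3.04 to 3.25) higher in the male library, and Kdm5b differed by 1.06-fold (1.04 to 1.08).

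Ranked by the ratio of SPM + 0.5, the largest differences towards the male library with at least 20 SPM, list members included, were those of the Y-linked genes Ube1y1 (a ratio of 4591, interval 1256 to 37490, on 2 fragments in the female library) and Eif2s3y (at least 995-fold), Dnmt3l, the peroxisomal transporter gene Abcd2 (at least 846-fold) and Tmc7 (a ratio of 1678, interval 383 to 11426, on 2 fragments). Towards the female library they were Ccdc79, whose product attaches meiotic telomeres to the nuclear envelope (270-fold, 188 to 394), Hist1h2ba, the class I histocompatibility gene H2-K1 (190-fold, 143 to 254, strain variants against the reference not tested), Inca1 (198-fold, 137 to 307) and Pcdh17 (689-fold, 185 to 5556, on few male fragments). The Y-linked genes Ddx3y and Kdm5d were listed at 0 in the female germ library, at least 467-fold and 244-fold lower. Of the genes that escape X inactivation, Kdm6a was 7.04-fold higher in female germ cells (6.58 to 7.53), Eif2s3x 1.28-fold higher (1.19 to 1.38) and Ddx3x 1.30-fold higher in male germ cells (1.24 to 1.36). Hprt, X-linked and on the housekeeping list, was 7.51-fold higher in the female library (7.10 to 7.94), and Rpl39l, a ribosomal protein gene copy active in the testis, 5.82-fold higher in the male library (5.26 to 6.46).

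By the size rule 1649 of 11766 genes (14.01%) were higher in male and 1180 (10.03%) in female germ cells. Under upper-quartile scaling the counts were 2103 and 861. With a minimum of 20 SPM the balance turned, to 856 and 911. Several somatic lists also stood higher in the male germ library: the Sertoli list had a median of 1.901, the fetal Leydig list 1.75 (2.37 with members listed at 0 at their bound), the stroma list 1.47 and the erythroid list 1.29 (1.73 with bounds, leaving out 1 gene at or under the floor in both). The pregranulosa list stood lower there, with 8 of 10 genes female-higher and a median of -1.02 (-1.35 with bounds), and the leukocyte list had a median of 0. Fgf9, on the Sertoli list, went the other way, 5.02-fold higher in the female germ library (3.72 to 6.88).

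**Figure D1:**
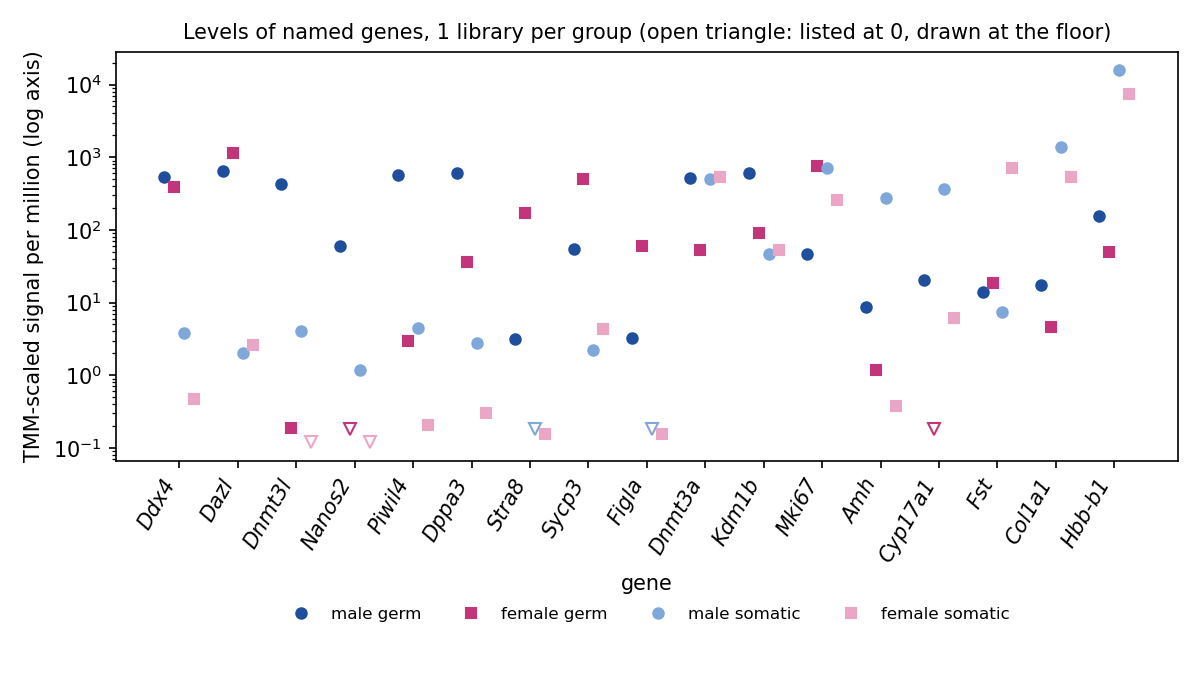
TMM-scaled signal (SPM, log axis) of 17 genes in the 4 libraries, 1 point per library, with genes listed at 0 drawn as open triangles at the floor of 3 fragments. Dnmt3l stands at 425 SPM in male germ cells and 0.187 in female germ cells, Stra8 at 3.19 and 171, and Fst reaches 704 in female somatic cells against at most 18.3 in another library.

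The number of genes with signal in each library was counted because the study's title speaks of transcription across many genes at a low level. At an equal 17.5 M fragments, 18004 genes were detected in male germ cells, 15589 in female germ cells, 15855 in male somatic cells and 15949 in female somatic cells. The male germ library thus held 2055 genes more than the next library. There were 1166 genes detected in male germ cells alone, against 108 in female germ, 65.4 in male somatic and 97.4 in female somatic cells alone, as means over draws. Without thinning, 3162 genes stood between 0.1 and 1 SPM in male germ cells against at most 2481 in another library, an excess of 681, and 14229 reached 1 SPM against at most 13362, an excess of 867. At 5 SPM or more there was no excess, with 11033 genes against 11324 in female somatic cells.

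Families of tissue-restricted genes showed it too. Of 1095 olfactory receptor genes, 240 (21.9%) were detected in male germ cells at equal depth, against 70 (6.39%) in female germ cells and 33.9 (3.10%) and 36.6 (3.34%) in male and female somatic cells. Their levels were low, with 5 receptors at 1 SPM or more in male germ cells and 9 in female germ cells. The first 3 by list order, Olfr1415, Olfr1413 and Olfr12, stood at 0.110, 0.0366 and 0.192 SPM in male germ cells and were listed at 0 in the other libraries. These values rest on 3, 1 and 5 fragments. Olfr1415 and Olfr1413 lay under the male germ floor of 0.113 SPM, and Olfr12 was 1.07-fold the female germ floor, with a counting interval from 0.575. Singly they cannot be told from the female germ library. Vomeronasal receptors were detected in 104 of 309 cases against at most 31.4 in another library, defensins in 19.06 of 55 against 8.43, keratin-associated protein genes in 4.27 of 52 against 1, and lens crystallins in 14.3 of 15 against 9.91. Their male over female germ medians were mostly like those of matched random lists. The percentiles were 13.7 for olfactory receptors, 51.2 for vomeronasal receptors, 10.1 for keratin-associated genes, 24.1 for crystallins and 98.6 for defensins. A threshold of 5 fragments left 16379 genes in male germ cells against at most 14702 elsewhere.

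**Figure D2:**
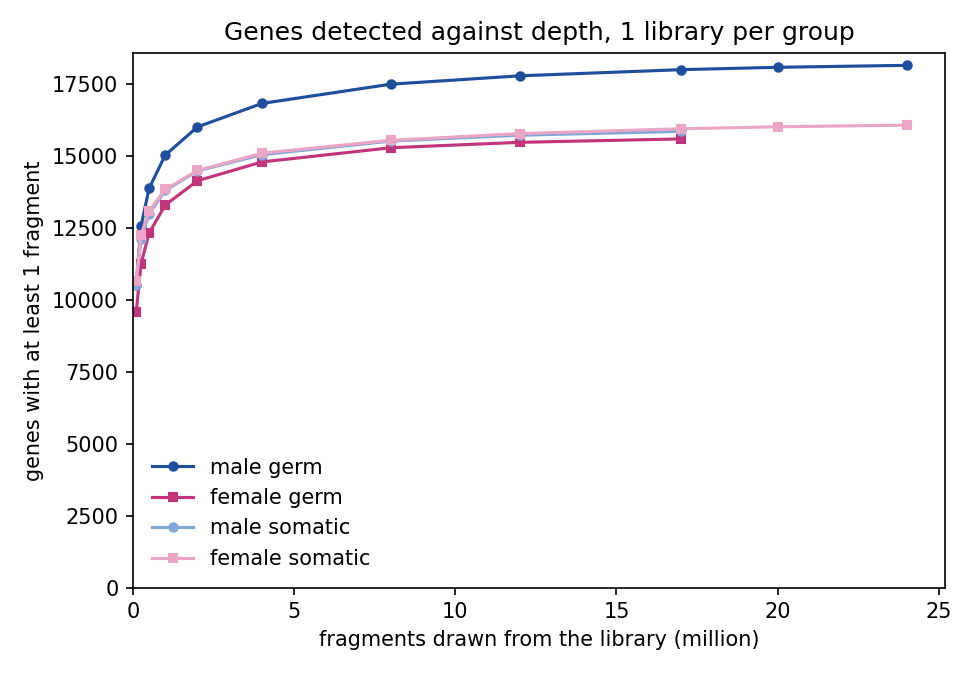
Number of genes with at least 1 fragment (vertical axis) in random draws of fragments from each library (horizontal axis, M fragments), 1 line per library. At the common depth of 17.5 M the male germ library reaches 18004 genes and the other 3 libraries lie between 15589 and 15949.

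Male and female somatic cells were compared to describe the supporting and steroid-producing cells of testis and ovary. Sertoli and fetal Leydig genes were higher in the male library and pregranulosa genes in the female. Amh, the anti-Müllerian hormone gene (chromosome 10, 80267992 to 80270393), stood at 273 SPM in male and 0.379 in female somatic cells, 719-fold higher (371 to 1426). Fst, the activin antagonist follistatin gene (chromosome 13, 115242469 to 115248938), was 94.7-fold higher in the female library (79.1 to 114), at 704 against 7.43 SPM.

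Of 15 Sertoli genes, 13 were at least 2-fold higher in the male library (median 4.31, percentile 100), with the hedgehog ligand gene Dhh at 383-fold (185 to 1104) and Sox9, the testis-determining transcription factor gene, at 2.36-fold (1.97 to 2.85). Of 8 fetal Leydig genes, 7 were (median 2.91, percentile 100). They included the steroidogenic enzyme genes Cyp17a1 at 60.5-fold (51.4 to 71.4) and Cyp11a1 at 192-fold (127 to 322), and Insl3 with a ratio of 133 (30.7 to 941) on 2 fragments in the female library. Of 10 pregranulosa genes, 9 were at least 2-fold higher in the female library (median -3.62, percentile 0), among them Foxl2, the ovarian transcription factor gene, at 50.6-fold (16.8 to 243), while Wnt4 differed by 1.59-fold (1.49 to 1.69).

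All 11 stroma genes were at least 2-fold higher in the male somatic library (median 1.75, percentile 100). Proliferation genes had a median of 0.85 and histone genes of 0.92, both at percentile 100, and 26 of 66 histone genes were at least 2-fold higher in the male library. Early response genes lay the other way, all 12 higher in the female library (median -0.94, percentile 0). Germ cell lists were mixed. In the male somatic library 15 of 17 piRNA genes and 6 of 9 germ cell core genes stood higher, each list with a median of 1.28, while the meiosis list had 6 male-higher and 13 female-higher genes (median -0.18) and the oocyte list a median of 0.01. The piRNA and core lists share Tdrd1, Rnf17 and Mael, and both medians are the value of Tdrd1. Piwil4 is on both the piRNA and the male germ program list. The male germ program had 5 of 7 genes at least 2-fold higher in the male somatic library (median 1.75, or 2.82 with bounds, leaving out 1 gene without a fold), and the pluripotency list 4 of 14 (median 0.35, or 1.21 with bounds, leaving out 2). The erythroid list had a median of 0.51 in which Klf1 went the other way, 13.01-fold higher in the female library (7.11 to 26.4).

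By the ratio of SPM + 0.5, the largest differences at 20 SPM or more also included Cbln1 (343-fold, 186 to 714) and the Y-linked Ddx3y (at least 995-fold) and Kdm5d (75.6 against 0.0195 SPM) towards males. Towards females they were the muscarinic receptor gene Chrm4 (207-fold, 123 to 416), Fam196b (320-fold, 122 to 1153), the homeobox gene Irx3 (at least 271-fold) and Calb1 (200-fold, 101 to 464). The imprinted genes Dlk1 and Plagl1 were 4.54-fold (4.28 to 4.81) and 4.08-fold (3.90 to 4.26) higher in the male library, and Rasgrf1 at least 26.2-fold. Padi6 was at least 13.96-fold higher in the female library. The escape genes Kdm6a, Eif2s3x and Ddx3x were 2.61-fold (2.42 to 2.81), 1.57-fold (1.51 to 1.64) and 1.40-fold (1.35 to 1.45) higher in the female library. Y-linked Eif2s3y stood at 39.6 against 0.0195 SPM.

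By the size rule 355 of 11835 genes (3%) were higher in male and 375 (3.17%) in female somatic cells, fewer than between the germ libraries. Leaving out the genes of the germ, blood and endothelial lists gave 349 and 373. Of the genes past the rule in both comparisons, 86 were male-higher in both, where independent lists would share 18.8, and 20 were female-higher in both, against 16.2. Genes typical of either male fraction also had low signal in the other, and the effect of this on the overlap was not tested. A further 57 were higher in male germ and female somatic cells, against 19.9, and 10 were higher in female germ and male somatic cells, against 15.4.

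**Figure D3:**
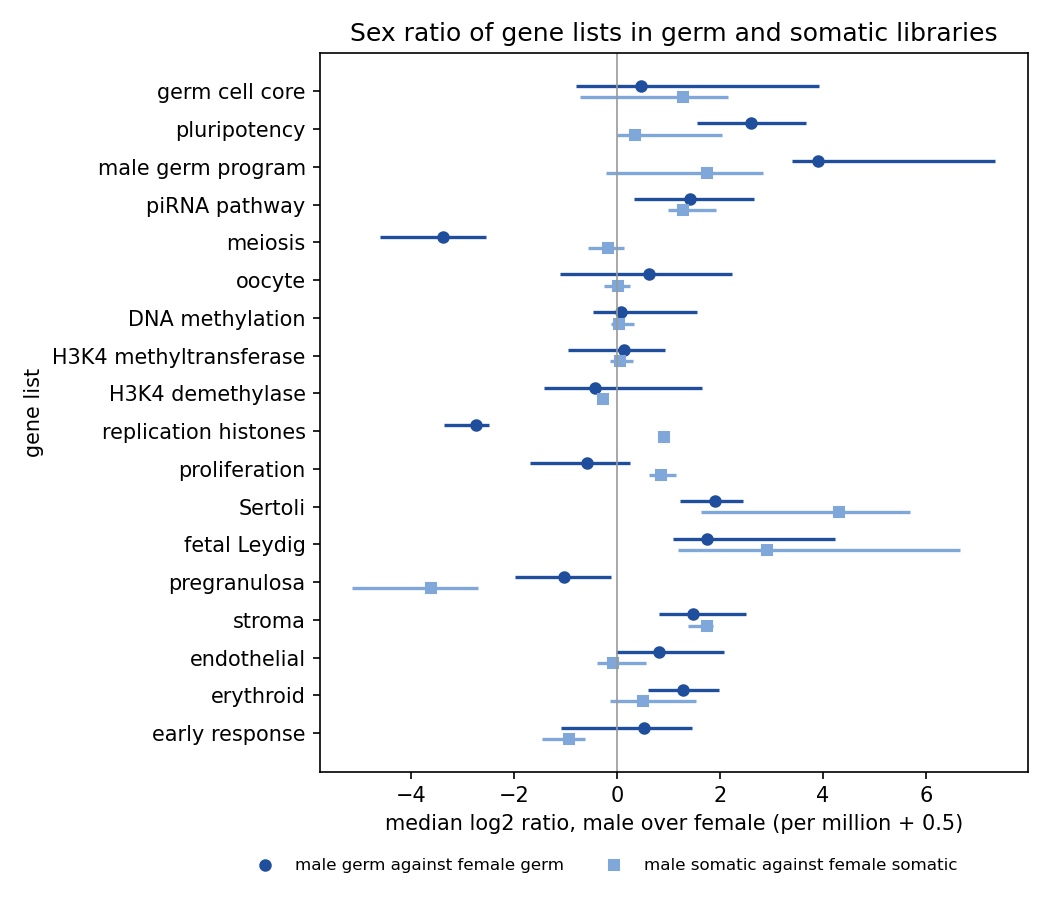
Median log2 ratio, male over female, of 18 gene lists in germ cells (circles) and somatic cells (squares), with 95% bootstrap intervals over list members. The meiosis list lies at -3.38 in germ cells and -0.18 in somatic cells, and the histone list at -2.74 and 0.92.

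The sex difference shared by germ and somatic cells was tested with cell type as a term. All genes that passed were higher in males, 19 of 14148 (limma adjusted p under 0.05), and 915 had an unadjusted p under 0.05. They were 5 Y-linked and 14 autosomal genes, with none on the X chromosome. Among the 10 with the smallest p were the Y-linked Ddx3y (log2 ratio 7.65 ± 0.98, limma adjusted p = 0.000302), Eif2s3y (7.38), Kdm5d (6.83), Uty (6.56) and Ube1y1 (6.86). The others were Cyp17a1 (5.60 ± 0.93, adjusted p = 0.00499), Cyp11a1 (5.57), the Sertoli gene Cst9 (5.38), Dnmt3l (6.24 ± 1.13, limma adjusted p = 0.0128) and Myof, a membrane repair gene, at 381 and 361 SPM in male germ and somatic cells against 2.15 and 85.6 in female (4.62 ± 0.82, adjusted p = 0.0111).

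Several of these genes were high in 1 male cell type and low in the other. Dnmt3l stood at 425 SPM in male germ and 4.10 in male somatic cells, and Cyp17a1 at 20.6 and 367. The germ cell core list stood in the male somatic library at a median of 0.798% of its male germ level, and the Sertoli and Leydig lists in the male germ library at 5.01% and 5.64% of their male somatic level. With 1 residual degree of freedom the fit took most of its spread from other genes. It called 7 genes under median-of-ratios factors, 0 under library totals, upper quartile or values as deposited (625, 651 and 677 at an unadjusted p under 0.05), 9 without the filter, 126 with a pseudocount of 0.1 (95 higher in males, 31 in females) and 0 without the term for cell type (59 unadjusted).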

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

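None of the groups held enough libraries to look for an outlying sample, and every deposited column entered the comparisons. The results below stand out because males exceeded females in 1 cell type and females exceeded males in the other. With 1 library per group the difference between the cell types was not tested, and no explanation was tested for them. The tests of carry-over between germ and somatic cells that follow were chosen only after the result was seen.

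The histone list had a median log2 ratio, male over female, of -2.74 in germ cells and 0.92 in somatic cells, a difference of -3.67, and 60 of its 66 genes were female-higher in germ and male-higher in somatic cells. Single genes of the cell cycle showed the same reversal: Mki67 with -3.9965 in germ and 1.44 in somatic cells (difference -5.43), Top2a with -1.77 and 1.25 (difference -3.02), and Bub1 with -1.25 and 1.65 (difference -2.90). The linker histone gene Hist1h1t had -3.71 and 1.203, a difference of -4.92. The mesonephric duct list, of 4 measured genes, had 1.53 in germ and -1.15 in somatic cells, a difference of 2.68, or 2.30 in germ cells with members listed at 0 at their bound and -1.92 in somatic cells without Lhx1, which was at or under the floor in both. Padi6, an oocyte gene, had 4.39 and -2.59, a difference of 6.98, from 9.97 SPM in male germ and 2.52 in female somatic cells and 0 in the other libraries. These log2 values rest on the pseudocount. Against the floors Padi6 was at least 55.5-fold higher in male germ and at least 13.96-fold higher in female somatic cells.

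Sertoli and Leydig genes had signal in the male germ library at a median of 5.01% and 5.64% of their male somatic level, while stroma genes stood at 1.28%, erythroid genes at 0.993%, leukocyte genes (4 members) at 4.48% and endothelial genes at 19.9%. In the female germ library pregranulosa genes stood at 3.06% of their female somatic level and stroma genes at 0.770%. Erythroid genes stood there at 0.909%, leukocyte genes (3 members) at 16.2% and endothelial genes at 8.36%. A higher share of supporting cell genes than of stroma genes was thus not particular to male germ cells. Somatic cells carried over in the proportions of the male somatic library would put the lists at an equal share. The ratio of the median share of Sertoli and Leydig genes to that of stroma genes was 4.19 (95% bootstrap interval 2.87 to 5.53, over 34 genes), which argues against that source for the whole signal. Carry-over of Sertoli and Leydig cells alone stays open: their shares had an interquartile ratio of 2.48 (1.25 to 5.90), an interval too wide to say whether they hold a single share, and 1 Sertoli gene, Dmrt1, is also a germ cell gene. Transcription of these genes in male germ cells is a candidate explanation that was not tested.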

How the results depend on the processing

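The alternatives with pseudocounts in the limma fits, with values as deposited, and without germ, blood and endothelial genes were chosen only after the result was seen. A planned count-based Wald test was not run because the values are not counts. No list median or named gene reversed its direction where it had been called. Scaling moved the median of all genes by over 0.1 in log2 in some comparisons: germ against somatic by 0.10 (median of ratios) and 0.16 (upper quartile), male against female germ by 0.16 (totals), 0.27 (upper quartile) and 0.11 (as deposited), and male against female somatic by -0.13 (totals). Signs of medians near 0 changed with scaling for maternally imprinted and ribosomal protein genes between germ cells, and for DNA methylation, H3K4 methyltransferase and housekeeping genes between somatic cells. Without Phlda2, at 0 in male and 0.175 SPM in female somatic cells and so under the male floor, the median of maternally imprinted genes between somatic cells went from -0.09 to 0.11.

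For germ against somatic, 1140 genes passed limma, and between 867 and 1102 did so under other scalings and pseudocounts, with 845 to 1072 of the 1140 kept. With no filter 0 passed (0 higher and 0 lower), with a smallest adjusted p of 0.0637 in limma, and the cause was not tested. With sex as a term 3049 passed (1094 higher, 1955 lower). Leaving out each library gave 349 to 4262 genes, 139 to 1754 higher and 186 to 2508 lower, with no sign changed among the tested calls. Of the 1140 calls, 270 of 1034 tested were kept without male somatic, 300 of 1034 without female somatic, 993 of 1004 without male germ and 909 of 1004 without female germ. Splitting the libraries by sex, or by sex and cell type crossed, called 0 genes each in limma (59 and 67 unadjusted). Both splits put a germ and a somatic library in each group, without a term for cell type. The difference between the cell types was then part of the spread, so these splits could hardly call a gene and are no check on the 1140 calls.

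The shared sex count of 19 became 7, 0, 0 and 0 under median-of-ratios, total, upper-quartile and as-deposited scaling, 9 without the filter, 126 (95 male-higher, 31 female-higher) at a pseudocount of 0.1, 14 at a pseudocount of 2, and 0 without the term for cell type. Without that term the difference between the cell types was part of the spread. The degrees of freedom borrowed from other genes were 25.7 in the main fit and 17.8, 7.64, 7.36 and 8.73 under those scalings, in the order above. They were 20.1 without the filter, without limit at a pseudocount of 0.1, and 31.6 at a pseudocount of 2. Calls thus mostly fell where fewer were borrowed, and why their number changed was not tested.

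Between germ cells, a 2-fold limit gave 3148 male-higher and 3094 female-higher genes, a minimum of 1 SPM 2737 and 1416, and a minimum of 20 SPM 856 and 911. Between somatic cells the counts were 1137 and 978 at 2-fold, 595 and 601 at 1 SPM, and 213 and 193 at 20 SPM. These limits set the count by construction. Male germ cells kept the highest detection under each alternative, by 1677 to 2088 genes, while the order of the somatic libraries turned at 5 fragments. The pluripotency median in germ against somatic was 6.62 and 2.95 at pseudocounts of 0.1 and 2, and the male germ program median between germ cells 2.69 at 2, because members near 0 depend on that constant. Depth limits genes under about 0.18 SPM in the female germ and male somatic libraries, where a gene at 0 cannot be told from one below the floor.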

Other observations

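The gene families in the first paragraphs were chosen after their values were seen. Of the tests below, only that of sequencing depth and the simulation of PCR copies were chosen after the result was seen.

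Genes were grouped into 424 families by symbol stem, with at least 5 members at 5 SPM or more. The Nlrp family, which includes oocyte maternal-effect genes, had the highest median of all families in male against female germ cells: all 7 members were at least 2-fold higher in males (median log2 ratio 4.32), led by Nlrp4c at 199 against 9.50 SPM, Nlrp4f at 125 against 3.55 and Nlrp14 at 101 against 5.21. Next came 5 Oas genes, antiviral oligoadenylate synthetase genes in a cluster on chromosome 5, all at least 2-fold higher in males (median 3.75) at levels up to 8.475 SPM. A member was counted if any library reached 5 SPM. All 5 Oas genes did so only in male germ cells, as did Nlrp2, Nlrp4e, Nlrp4f, Nlrp5 and Nlrp9b. For these genes the limit itself fixed the direction between germ cells, and the family medians and ranks rest on it too. The Rhox homeobox cluster on the X chromosome went the other way. Of 9 members, 8 were at least 2-fold higher in females, such as Rhox13 at 87.4 against 8.43 SPM and Rhox9 at 41.5 against 0.923, and 1, Rhox10, stood at 32.03 in male germ cells and was listed at 0 in female germ cells. Rhox1, Rhox2a, Rhox2b, Rhox2e, Rhox6 and Rhox9 reached 5 SPM only in female germ cells, and Rhox10 only in male germ cells. Among the X-linked Xlr genes, Xlr (28.4 against 5.48 SPM), Xlr4a, Xlr4b and Xlr4c were higher in female germ cells (214 against 16.5, 158 against 22.6, and 236.5 against 14.7), while Xlr3 and Xlr5 members were within 2-fold. Members of these families are similar in sequence and their reads cannot be assigned to a single copy with certainty, so single values are uncertain.

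Subunits of the cytosolic chaperonin were higher in germ cells, all 8 Cct genes with a median of 1.64 in germ against somatic cells, and Cct8 stood at 2844 SPM in male germ, 950 in female germ, 392 in male somatic and 368 in female somatic cells. In female germ cells 7 of 8 augmin genes (Haus), which nucleate spindle microtubules, were higher than in male germ cells (median -1.49), as were 9 of 10 Ndufb subunit genes of respiratory complex I (median -1.24). The class I gene H2-D1 went with H2-K1, at 233 SPM in female germ cells and 3.31, 6.70 and 8.44 in male germ, male somatic and female somatic cells, while B2m, which encodes their light chain, stood at 10.8 in female and 23.4 in male germ cells. Class I genes vary between strains, and variants of this cross against the reference were not tested. Between somatic cells the Hoxd genes had the highest family median, with 5 of 6 at least 2-fold higher in males (median 1.47) and Hoxd4 at 88.3 against 34.1 SPM. All 11 stroma genes were also at least 2-fold higher in males there (median 1.75).

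The male germ library held signal in more genes than the other libraries. Sequencing depth does not account for this, since at equal fragments it still detected 12.9% more genes than the next library. RNA from somatic cells is also argued against as the whole cause: of the 2607 genes detected in the male and not in the female germ library, 58.2% (57.9 to 58.6 over draws) had any signal in a somatic library. Genomic DNA stays open. Olfactory receptor genes without the 5% highest had an index of dispersion of 2.82 (2.60 to 3.04) around a single rate per length, over 1040 genes. The bar of 2 set for that index took no account of PCR copies, which cannot be separated here. A single rate with 3 copies of each molecule on average gave 3.66 in simulation. The simulated values kept their 5% highest, so 3.66 and 2.82 are not like for like and the simulation cannot decide the question. A property of this library, such as its preparation, cannot be told apart from a property of male germ cells with 1 male germ library, and low-level transcription of many genes in male germ cells stays a hypothesis.

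X-linked genes were higher as a set in the female germ library relative to autosomal genes, by 0.45 in median log2 ratio (95% bootstrap interval 0.21 to 0.63, 586 X-linked genes). The interval is over genes of 1 pair of libraries. Female-higher were 55.5% of X-linked and 47.4% of autosomal genes, so many X-linked genes went the other way. The autosomes had male over female medians between -0.10 and 0.31. A scaling factor per library moves all chromosomes alike and cannot give the difference between the X-linked and the autosomal median. A sex difference of X-linked genes common to all cells is argued against, since the same measure between the somatic libraries was 0.0368 (-0.02 to 0.09, 492 genes). A higher X-linked output in female germ cells, in which the inactive X chromosome is known to be reactivated, is a candidate explanation, and germ cell genes clustered on the X chromosome, such as the Rhox and Xlr4 genes, may contribute. With 1 library per group neither was tested.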
